A study of Homo sapiens with 6 samples.

How the data were processed

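PolyA RNA of U87 cells was isolated with TRIzol and a column kit, made into strand-directional libraries and sequenced as paired reads of 75 bases, per the labels' protocols. The series holds 6 libraries, 3 transfected with siGL2 and 3 with a combination of 2 siRNAs against LINC00152, and each library's group and letter were taken from its title. The deposited values are whole-number counts per gene symbol, not normalized, in a table for each library. The tools bcl2fastq, HISAT, HTSeq and DESeq and the genome build hg38 are named, without versions, per the submitters' processing notes. The annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here, so tested genes named here are reported with the share of their 75-base stretches or exonic bases that other genes hold on either strand, where it is at least 10%. For SOD2 no share was computed.

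Everything else was computed from the deposited counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 14078 of 27192. Library sizes were scaled by TMM, with factors of 1.02 to 1.03 in the siGL2 libraries and 0.975 to 0.979 in the siLINC00152 libraries. Groups were compared with edgeR's robust quasi-likelihood test on all 6 libraries with no covariate, and p-values were adjusted by the Benjamini-Hochberg method. All tests were two-sided. The standard error of a log2 fold change is its size divided by the square root of its F statistic. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. With total counts of 41963120 to 46234763, a gene with 0 counts may stand at up to 3 counts, or 0.0649 to 0.0715 CPM, which covers counting error only. The most abundant gene took 0.864% to 0.938% of a library and the 20 most abundant took 8.91% to 9.13%. The mitochondrial ribosomal RNA genes took 0.681% to 0.867%.

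Replicates were compared by a chi-square of their counts over genes. Chi-square per degree of freedom was between 2.91 and 13.7 over the 6 pairs within groups, so no pair agreed within sampling noise. It was 10.9 and 13.7 for siGL2 replicate A against B and C, and 2.91 for B against C.

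Before the data were examined, the design, the alternatives, 29 gene lists (621 symbols, 16 of them in more than 1 list), markers of 6 cell types and the rule for named genes were fixed. The lists covered epithelial-mesenchymal transition and invasion, collagens and matrix, integrins and focal adhesion, mesenchymal and proneural glioblastoma, G1/S, G2/M, p53 targets, apoptosis, interferon, NF-kB, the unfolded protein response, ATF4, hypoxia and glycolysis, cholesterol and fatty acid synthesis, NRF2, heat shock, YAP/TEAD, TGF-beta and BMP, MAPK output, RNA interference machinery, lysosome and autophagy, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, other long noncoding RNAs and genes linked to LINC00152 elsewhere. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry. The rule named LINC00152 and MIR4435-2HG, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 10 CPM and no overlap between groups, up to 4 members of each list with the smallest p, tested genes within 1 Mb of LINC00152, and the most abundant marker of each cell type. Members that went against their list or did not pass, and markers other than the most abundant, were named after their values were seen. A few genes and 1 list that the rule names are not reported here.

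Coordinates come from GENCODE release 29 on GRCh38, the assembly that hg38 names. Of 27192 symbols, 24706 were matched to a gene, 550 of them through another symbol. Transcript sequences of that release gave the share of 75-base stretches that a gene has in common with other genes and the 3′ UTR sequences. No genome sequence was used here. In 11337 genes of at least 1 CPM with an annotated 3′ UTR, log2 fold changes were adjusted for 3′ UTR length and GC content, and each of 16149 words of 7 bases present in at least 50 genes was given a z-score for the mean adjusted change of the genes that hold it. The z-scores were set beside those of 100 shuffles of the values among genes of similar 3′ UTR length and GC content, and counts of genes that hold the leading words beside 100 shuffles in which those words were picked again.

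The scripts were tested on simulated data. With 50 genes changed at each of 4 fold sizes in a simulation of this comparison over 13985 tested genes, the edgeR step recovered 62% of 1.25-fold, 76% of 1.5-fold, 86% of 2-fold and 100% of 4-fold changes, and called 9 of 13785 unchanged genes. With no gene changed it called 0. Each list test recovered 10 of 10 lists shifted by 0.3 on the log2 scale. There every member of a list shifted alike and no gene outside those lists changed. In the real comparison most tested genes passed and members of a list went both ways, a setting that was not simulated. The simulated genes varied independently, whereas the estimated correlation in the ribosomal protein list was 0.781, so performance with correlated members was not tested. The word search put 20 of 20 planted words first. The planted change was −0.4 on the log2 scale, against mean adjusted changes of −0.11 for GTGTGTC and 0.10 for TGGTGCT, the words with the lowest and highest z. Recovery at that smaller size was not tested. Alternatives were other size factors, library size alone, DESeq2, limma-voom, other filters on low counts, the letter as a block, each library left out, the 20 most abundant genes left out of library sizes, corrections for GC content and gene length (known for 96.4% of tested genes), a test against a 1.5-fold change, and the other list tests.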

Results

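RNA was measured in 6 libraries from U87, an established human glioblastoma cell line, to learn how its transcriptome differs when the long noncoding RNA LINC00152 is knocked down. Cells were transfected 2 times, 24 hours apart, either with a pair of siRNAs against LINC00152 or with siGL2, which the labels give as a nonspecific control siRNA, and were collected 24 hours after the last transfection. Each group held 3 libraries, named A, B and C. The total count per library was 42474451, 42139419 and 46234763 in the siGL2 libraries and 41963120, 42999222 and 43713662 in the siLINC00152 libraries, and between 17741 and 17877 genes had at least 1 count. Of 27192 genes listed, 14078 had enough counts to be tested. Nothing in the labels says whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

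LINC00152 fell 5.68-fold in the siLINC00152 libraries, to 17.6% of its control level. Its counts were 650, 608 and 776 in the siGL2 libraries against 114, 112 and 109 in the siLINC00152 libraries, or 15.2 ± 1.18 against 2.67 ± 0.108 CPM (TMM-scaled counts relative to library size; SD, n = 3). The log2 fold change was −2.51 ± 0.09 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.55e-15). LINC00152 (CYTOR in current nomenclature, ENSG00000222041.11) is annotated as a long intergenic noncoding RNA on the plus strand of chromosome 2, from 87454781 to 87636740 (hg38). MIR4435-2HG, a close copy of LINC00152 on the minus strand of chromosome 2 from 111036776 to 111523376, stood at 39.0 ± 1.31 CPM in the control and 37.7 ± 1.05 CPM after knockdown (SD, n = 3). Its log2 fold change of −0.05 ± 0.05 (SE) had a 95% confidence interval of −0.15 to 0.06 and did not pass the test (edgeR adjusted p = 0.429). Of the 75-base stretches of annotated LINC00152 transcripts, 13.1% also occur in MIR4435-2HG (35.4% in the 3 transcripts tied to RefSeq), and 17.7% of those of MIR4435-2HG occur in LINC00152, so reads from these parts could be assigned to either gene or to neither. With a correction for gene length, MIR4435-2HG passed the test at a log2 fold change of −0.16 (edgeR adjusted p = 0.0084).

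**Figure D1:**
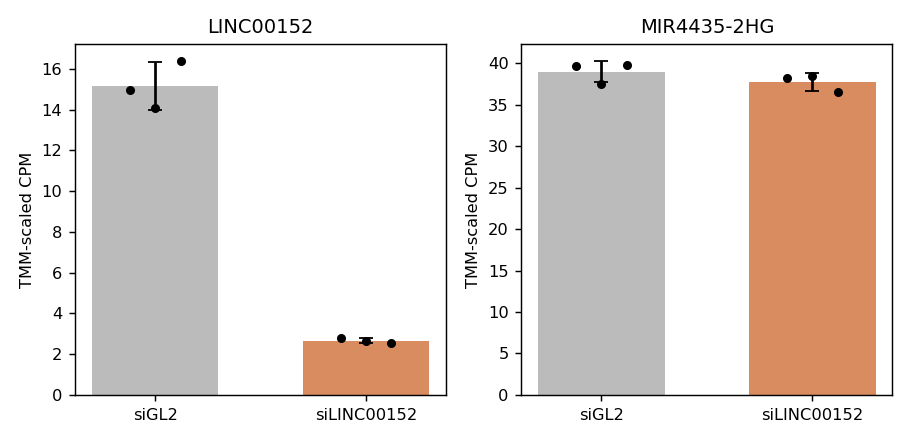
TMM-scaled CPM of LINC00152 and MIR4435-2HG by siRNA group. Bars are means, error bars SD and points the 3 libraries of each group. LINC00152 averaged 15.2 CPM with siGL2 and 2.67 CPM with siLINC00152, while MIR4435-2HG averaged 39.0 and 37.7 CPM.

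The transcriptome differed broadly between the groups, mostly by small amounts. At an adjusted p under 0.05 (edgeR), 4529 genes were higher and 4529 lower after knockdown, together 64.3% of the tested genes. Of these 9058 genes, 6248 (69.0%) differed by less than 1.5-fold, and 931 differed at least 2-fold, 434 of them upward and 497 downward. The first principal component separated the groups and held 80.01% of the variance. The lowest correlation of log CPM between libraries of a group was 0.996, and the highest between groups was 0.982. The biological coefficient of variation was 4.47%, and the median standard error of a log2 fold change was 0.06. When library size alone set the scale, in place of TMM, the median log2 fold change moved by −0.07 and the split became 3755 genes higher and 5389 lower.

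**Figure D2:**
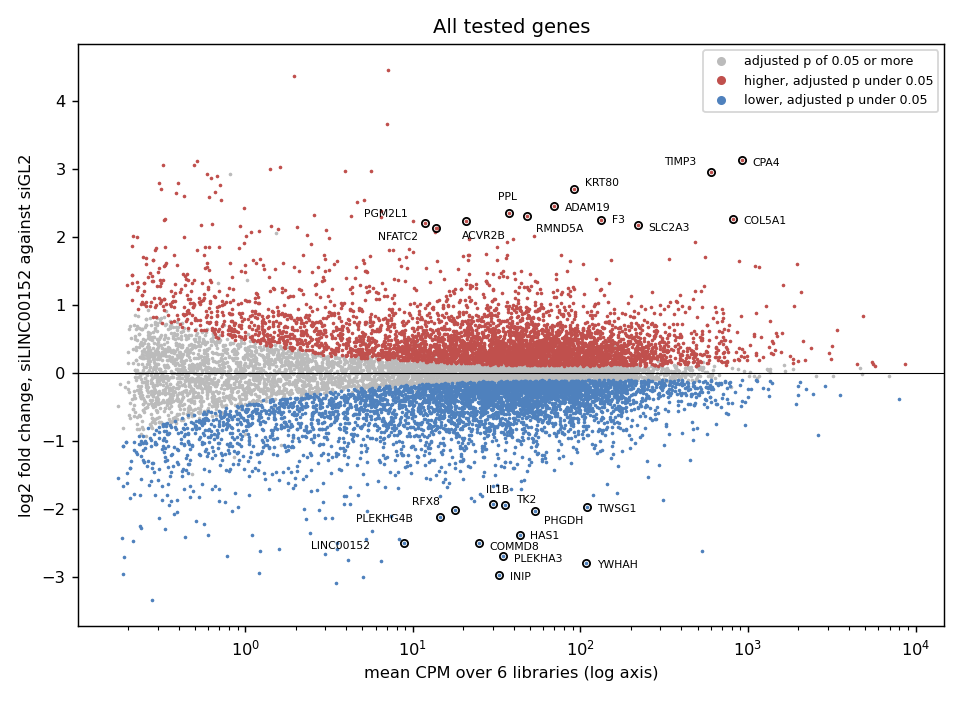
Log2 fold change (siLINC00152 against siGL2, 3 libraries each) of the 14078 tested genes against their mean CPM over the 6 libraries, on a log axis. Red and blue points are the 4529 genes higher and the 4529 lower at an adjusted p under 0.05. Circles mark LINC00152 at −2.51 and the 12 largest rises and 11 of the 12 largest falls among genes of at least 10 CPM, from CPA4 at 3.12 to INIP at −2.97.

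Among genes with a mean of at least 10 CPM, the largest rise was in CPA4, which encodes a carboxypeptidase (chromosome 7, 130293134 to 130324180). CPA4 rose 8.72-fold, from 189.5 ± 5.69 to 1653 ± 157 CPM (SD, n = 3; edgeR adjusted p = 1.94e-18). TIMP3, an inhibitor of matrix metalloproteinases (chromosome 22, 32801701 to 32863043), rose 7.77-fold, from 137 ± 3.53 to 1069 ± 41.6 CPM (SD, n = 3; edgeR adjusted p = 3.09e-20). The next largest rises were in the keratin gene KRT80 (log2 fold change 2.70 ± 0.06, SE), the metalloproteinase gene ADAM19 (2.46 ± 0.06), the periplakin gene PPL (2.36 ± 0.07) and RMND5A, which encodes a ubiquitin ligase subunit (2.31 ± 0.06). COL5A1, a chain of type V collagen, rose by 2.27 ± 0.05 and F3, tissue factor, by 2.26 ± 0.06. The activin receptor gene ACVR2B (2.23 ± 0.10), PGM2L1 (2.21 ± 0.07), the glucose transporter gene SLC2A3 (2.17 ± 0.05) and the transcription factor gene NFATC2 (2.14 ± 0.09) completed the 12. The edgeR adjusted p of these 12 genes was 8.81e-12 or lower. In SLC2A3, 8.11% of 75-base stretches also occur in other genes, mainly SLC2A14.

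The largest fall was in INIP, which encodes a subunit of a single-strand DNA binding complex (chromosome 9, 112683926 to 112718236, minus strand). INIP fell 7.81-fold, from 58.2 ± 1.05 to 7.45 ± 0.244 CPM (SD, n = 3; edgeR adjusted p = 6.12e-19). YWHAH, an adaptor that binds phosphorylated proteins (chromosome 22, 31944461 to 31957603), fell 6.94-fold, from 189 ± 8.42 to 27.2 ± 1.08 CPM (SD, n = 3; edgeR adjusted p = 2.55e-19). PLEKHA3 (log2 fold change −2.70 ± 0.06, SE) and COMMD8 (−2.50 ± 0.08) followed, then the hyaluronan synthase gene HAS1 (−2.39 ± 0.07) and PLEKHG4B (−2.12 ± 0.07). PHGDH, the enzyme that opens the serine synthesis pathway, fell by 2.04 ± 0.06, RFX8 by 2.02 ± 0.07 and TWSG1, a modulator of BMP signalling, by 1.97 ± 0.05. TK2, a mitochondrial thymidine kinase, fell by 1.94 ± 0.05 and the cytokine gene IL1B by 1.93 ± 0.07. In TK2, 21.9% of exonic bases overlap genes of the opposite strand, and the strand setting of the counting is not given in the sources used here. Of the 12 largest falls, 11 of which are named here, 8 hold in their 3′ UTR at least 1 of the 4 words of 7 bases with the lowest z (GTGTGTC, TGAAAGA, TGTGTCA and CTGAAAG), and so do 7 of the 12 largest rises, whose 3′ UTRs are longer (median 3095.5 against 833 bases). Among all genes searched, 167 of 300 that fell at least 2-fold held any of these words, with 113.8 expected as the mean of 100 shuffles within similar 3′ UTR length and GC content, against 126 of 266 that rose at least 2-fold, with 125.65 expected. The words were chosen on these same changes.

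Genes of DNA replication and mitosis fell together. In the G1/S and DNA replication list, 26 of 29 tested members fell, 2 rose and 1 did not pass, with a median log2 fold change of −0.71 (camera adjusted p = 5.09e-16; adjusted p = 0.200 with an estimated correlation). The transcription factor gene E2F1 fell by 1.16 ± 0.05 on the log2 scale (SE), the replicative helicase gene MCM3 by 1.03 ± 0.04, the origin licensing factor gene CDC6 by 1.01 ± 0.05 and the uracil glycosylase gene UNG by 0.89 ± 0.05. The 2 that rose were CDC25A (0.24 ± 0.05) and CCNE1 (0.17 ± 0.06), and GINS1 stood at 0.02 ± 0.05. In the G2/M and mitosis list, 27 of 28 members fell, with a median of −0.38 (camera adjusted p = 1.42e-06; adjusted p = 0.369 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell by 0.84 ± 0.05, BIRC5 (survivin) by 0.68 ± 0.04, CCNB1 (cyclin B1) by 0.63 ± 0.04 and the mitotic kinase gene AURKA by 0.57 ± 0.04. CCNA2 stood at −0.01 ± 0.05.

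Targets of p53 rose in the same comparison. Of 27 members, 20 rose, 2 fell and 5 did not pass, with a median log2 fold change of 0.36 (camera adjusted p = 1.42e-06; adjusted p = 0.527 with an estimated correlation). BTG2, an antiproliferative gene, rose by 2.07 ± 0.08 (SE), TP53INP1 by 1.36 ± 0.05, the stress sensor SESN1 by 1.16 ± 0.07 and the polo-like kinase gene PLK2 by 1.04 ± 0.06. The 2 that fell were TP53I3 (−0.41 ± 0.07) and CDKN1A, the cyclin-dependent kinase inhibitor p21 (−0.13 ± 0.05). The 5 that did not pass, XPC, RRM2B, GDF15, ZMAT3 and BAX, lay within 0.06 of 0. In XPC, 30.4% of exonic bases overlap genes of the opposite strand. Apoptosis regulators went both ways, with 8 of 18 higher and 6 lower, and the list did not pass (camera adjusted p = 0.467). In a fit chosen after the results were seen, without genes that hold any of the 4 words with the lowest z, it passed with a median of 0.07 over 14 members (camera adjusted p = 0.0461; adjusted p = 0.289 with an estimated correlation). Among the 18, BMF rose by 2.51 ± 0.11 and BIRC3 by 1.54 ± 0.07.

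Hypoxia and glycolysis genes and genes of the unfolded protein response were higher after knockdown. In the hypoxia and glycolysis list, 19 of 23 members rose, 1 fell and 3 did not pass, with a median log2 fold change of 0.37 (camera adjusted p = 9.17e-07; adjusted p = 0.212 with an estimated correlation). The prolyl hydroxylase gene EGLN3 rose by 1.66 ± 0.06 (SE), the glucose transporter gene SLC2A1 by 1.21 ± 0.05, NDRG1 by 1.20 ± 0.05 and the adrenomedullin gene ADM by 0.61 ± 0.04. BNIP3 fell by 0.32 ± 0.05, and ALDOA, TPI1 and ENO1 lay between −0.05 and 0.06. In the unfolded protein response list, 15 of 19 members rose, with a median of 0.47 (camera adjusted p = 2.58e-05; adjusted p = 0.212 with an estimated correlation). The chaperone gene DNAJB9 rose by 1.75 ± 0.07, the transcription factor gene XBP1 by 0.92 ± 0.05, HYOU1 by 0.73 ± 0.04 and HERPUD1 by 0.62 ± 0.05. MANF fell by 0.51 ± 0.05 and HSPA5, the main chaperone of the endoplasmic reticulum, by 0.10 ± 0.04, while DNAJC3 (0.09 ± 0.04) and DDIT3 (−0.01 ± 0.07) did not pass. ATF4 targets did not pass as a list, with 9 of 25 members higher, 6 lower and 10 not passing (camera adjusted p = 0.557). Within it the enzymes of serine and one-carbon metabolism PHGDH (−2.04 ± 0.06) and MTHFD2 (−1.30 ± 0.05) fell, whereas the secreted glycoprotein gene STC2 (0.80 ± 0.05) and SESN2 (0.78 ± 0.05) rose. Of exonic bases, 33.2% in MTHFD2, 31.6% in DDIT3 and 13.3% in ALDOA overlap genes of the opposite strand, and 35.1% of the 75-base stretches of ALDOA also occur in other genes.

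Genes of the extracellular matrix, its receptors and the YAP/TEAD programme were higher on balance. Of 22 collagen and matrix genes, 14 rose, 5 fell and 3 did not pass, with a median log2 fold change of 0.47 (camera adjusted p = 4.11e-04; adjusted p = 0.531 with an estimated correlation). Beside COL5A1, the type I collagen gene COL1A2 rose by 0.98 ± 0.05 (SE) and the collagen prolyl hydroxylase gene P4HA2 by 0.96 ± 0.04. The proteoglycan gene LUM fell by 1.92 ± 0.11, and THBS2, LAMA4, LAMB1 and COL4A2 also fell. COL6A3, THBS1 and NID1 did not pass, at −0.05, −0.06 and −0.15. In a fit chosen after the results were seen, without genes whose 3′ UTR holds the word TGGTGCT, 9 of the 22 members were left, with a median of 0.38, and the list did not pass (camera adjusted p = 0.172). Of 25 integrin and focal adhesion genes, 12 rose, 4 fell and 9 did not pass, with a median of 0.12 (camera adjusted p = 0.00158; adjusted p = 0.531 with an estimated correlation). That median was 0.06 with library size alone and 0.07 without siGL2 replicate C. The integrin genes ITGA6 (2.30 ± 0.11), ITGA5 (1.61 ± 0.05) and ITGAV (0.99 ± 0.05) and the caveolin gene CAV1 (0.98 ± 0.04) rose, and ITGA2, ITGB3, ITGA4 and PARVA fell. Of 22 YAP/TEAD targets, 14 rose, 6 fell and 2, GADD45B (0.15 ± 0.07) and ARHGEF17 (0.14 ± 0.09), did not pass, with a median of 0.33 (camera adjusted p = 1.42e-04; adjusted p = 0.369 with an estimated correlation). Beside F3, the growth factor gene TGFB2 rose by 1.35 ± 0.06, IGFBP3, which binds insulin-like growth factors, by 1.29 ± 0.05 and the receptor tyrosine kinase gene AXL by 0.84 ± 0.04. Of 75-base stretches, 24.8% in TGFB2 also occur in other annotated genes, mainly TGFB2-OT1, and 50.5% in ITGB3 do, mainly in AC068234.1.

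Genes of epithelial-mesenchymal transition and invasion went both ways. Of 25 members, 14 rose, 10 fell and 1, S100A4 (0.13 ± 0.15), did not pass, and the list did not pass (camera adjusted p = 0.108). The matrix protein gene SPARC rose by 1.56 ± 0.04 (SE), the lysyl oxidase gene LOX by 1.09 ± 0.04 and TGFBI by 0.84 ± 0.04. PLAU, the urokinase plasminogen activator, fell by 1.87 ± 0.05, from 488 ± 13.6 to 134 ± 6.36 CPM (SD, n = 3). In PLAU, 31.1% of exonic bases overlap genes of the opposite strand. All 16 TGF-beta and BMP targets passed the test singly, 11 upward and 5 downward, but the list did not (camera adjusted p = 0.420). Without genes whose 3′ UTR holds TGGTGCT, a fit chosen after the results were seen, it passed with a median of 0.33 over 13 members, against 0.21 over all 16 (camera adjusted p = 0.0191; adjusted p = 0.433 with an estimated correlation). PMEPA1 (0.87 ± 0.06) and SKIL (0.79 ± 0.05) rose, and ID1, a target of BMP signalling, fell by 1.15 ± 0.05.

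Nuclear-encoded genes of oxidative phosphorylation fell slightly. Of 31 members, 19 fell, 1 rose (NDUFA4, 0.14 ± 0.05, SE) and 11 did not pass, with a median log2 fold change of −0.18 (camera adjusted p = 0.00627; adjusted p = 0.795 with an estimated correlation). UQCRB fell by 0.88 ± 0.06, CYC1 by 0.55 ± 0.05, ATP5A1 by 0.53 ± 0.04 and NDUFS3 by 0.43 ± 0.05. In NDUFS3, 16.1% of 75-base stretches also occur in PTPMT1 or other genes. None of the 13 mitochondrially encoded genes of the fixed list was present under its symbol in the tables used here. Of 32 ribosomal protein genes, 16 fell and 16 did not pass, with a median of −0.12 (camera adjusted p = 0.122). Those with the smallest p were RPL4 (−0.42 ± 0.04), RPS27A (−0.64 ± 0.06), RPL3 (−0.27 ± 0.04) and RPS23 (−0.27 ± 0.05), and between 3.41% and 7.76% of their 75-base stretches also occur in other genes, mainly pseudogenes. Without siGL2 replicate A the ribosomal list passed (camera adjusted p = 0.00392; adjusted p = 0.635 with an estimated correlation).

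Signalling outputs were mixed. Of 19 genes of MAPK output, 12 fell and 6 rose (camera adjusted p = 0.122). The feedback inhibitor gene SPRY4 (−1.59 ± 0.06, SE) and the immediate early gene EGR1 (−1.50 ± 0.07) fell, while the phosphatase gene DUSP5 rose by 1.46 ± 0.05 and SPRY2 by 0.75 ± 0.05. Of 22 interferon response genes, 13 fell, 5 rose and 4 did not pass (camera adjusted p = 0.108). IFI44L (−1.20 ± 0.07), OASL (−0.89 ± 0.07), HERC5 (−0.82 ± 0.08) and IFI44 (−0.81 ± 0.06) fell, and the 5 that rose were IFIH1, DDX58, OAS1, DDX60 and IFIT2. NF-kB and cytokine genes were evenly split, with 8 of 22 higher and 8 lower (camera adjusted p = 0.817). Here the cytokine genes IL1B (−1.93 ± 0.07) and CSF3 (−1.80 ± 0.07) and the mitochondrial superoxide dismutase gene SOD2 (−1.12 ± 0.05) fell, whereas IL1A rose by 1.81 ± 0.08.

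Lipid and stress-defence lists did not pass. Cholesterol synthesis genes had 7 of 23 members higher and 11 lower (camera adjusted p = 0.857), with INSIG1 (0.97 ± 0.04, SE), HMGCS1 (0.81 ± 0.05) and SC5D (0.54 ± 0.06) higher and PMVK lower (−0.61 ± 0.06). Of 11 fatty acid synthesis genes, 3 rose and 6 fell (camera adjusted p = 0.611). SCD (1.05 ± 0.06), SREBF1 (0.73 ± 0.06) and ACLY (0.31 ± 0.04) rose, and the desaturase gene FADS1 fell by 1.43 ± 0.05 and the elongase gene ELOVL5 by 0.36 ± 0.05. Of 17 NRF2 targets, 6 rose and 5 fell (camera adjusted p = 0.973), among them AKR1B10 (1.30 ± 0.06) upward and HMOX1 (−0.75 ± 0.05), NQO1 (−0.56 ± 0.05) and GCLM (−0.53 ± 0.05) downward. Genes of the opposite strand overlap 17.7% of exonic bases in NQO1 and 14.95% in HMGCS1. Of 14 heat shock genes, 2 rose and 6 fell (camera adjusted p = 0.433). The collagen chaperone gene SERPINH1 rose by 1.15 ± 0.05 and HSPB1 by 0.30 ± 0.05. HSP90AA1 (−0.91 ± 0.05), HSPD1 (−0.45 ± 0.05) and HSPH1 (−0.36 ± 0.05) fell.

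Neither glioblastoma subtype list passed. Of 20 mesenchymal genes, 12 rose and 5 fell (camera adjusted p = 0.245), with BHLHE40 (0.70 ± 0.05, SE), STAT3 (0.67 ± 0.05), RUNX1 (0.57 ± 0.05) and LGALS3 (0.56 ± 0.05) higher and CEBPB, CASP1, CHI3L1, CD44 and ANXA1 lower. Only 8 of 20 proneural genes could be tested (camera adjusted p = 0.857). SOX4 rose by 0.45 ± 0.09 and PDGFRA fell by 0.59 ± 0.11 and TCF4 by 0.16 ± 0.05. TCF4 no longer passed without siLINC00152 replicate A (−0.11, edgeR adjusted p = 0.0586). In PDGFRA, 14.7% of 75-base stretches also occur in another annotated gene. Among 10 tested genes that have been linked to LINC00152 in other systems, 2 rose, 5 fell and 3 did not pass (camera adjusted p = 0.246). The notch receptor gene NOTCH1 fell by 1.14 ± 0.10, the survival gene MCL1 by 0.81 ± 0.04 and the cyclin D1 gene CCND1 by 0.48 ± 0.04. HIF1A (−0.12 ± 0.05) and CDKN1A also fell, AKT2 (0.39 ± 0.05) and CDC25A rose, and EGFR (−0.07 ± 0.18) and EPCAM (0.00 ± 0.19) were among those that did not pass. Genes of the opposite strand overlap 10.3% of exonic bases in CCND1 and 11.8% in CEBPB.

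**Figure D3:**
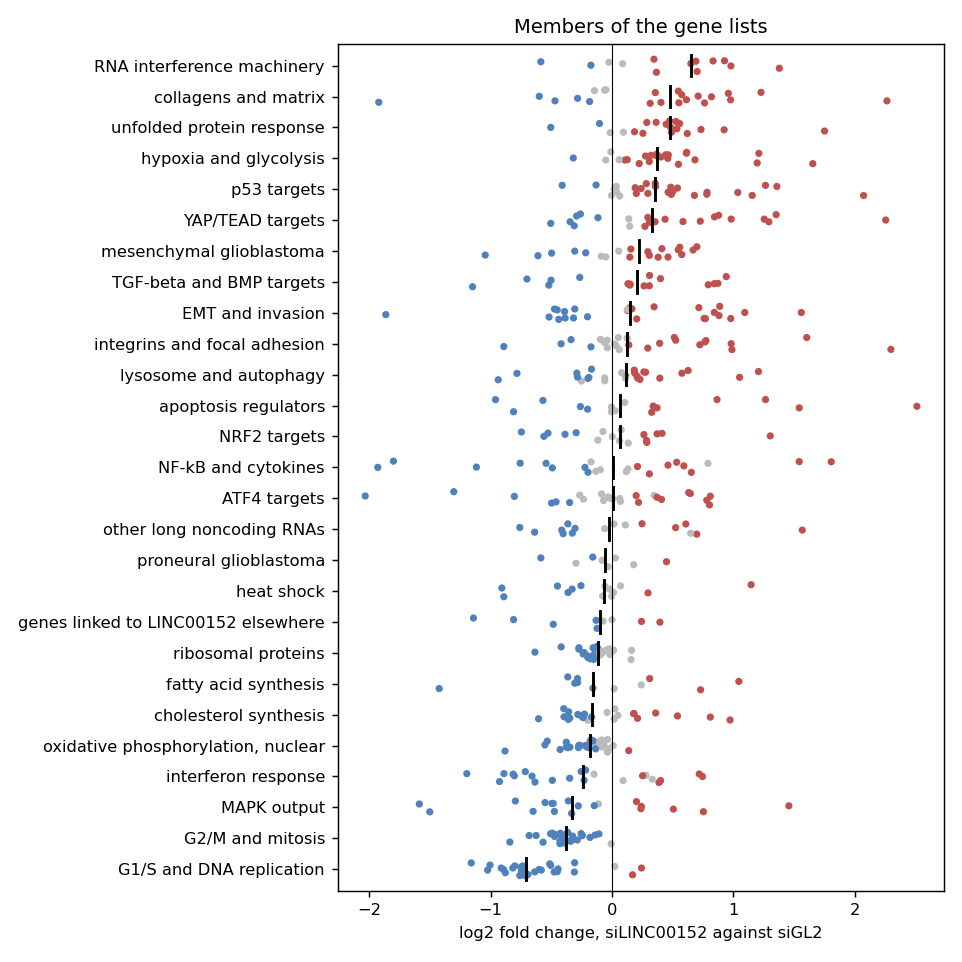
Log2 fold change (siLINC00152 against siGL2, 3 libraries each) of the tested members of 27 of the 28 gene lists with at least 5 tested members. Points are genes (a few are left out), red or blue when higher or lower at an adjusted p under 0.05 and grey otherwise, and black bars are list medians, from −0.71 for G1/S and DNA replication to 0.65 for RNA interference machinery.

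By camera with a preset correlation of 0.01, 10 of the 28 lists passed at an adjusted p under 0.05, 7 upward and 3 downward. With a correlation estimated from these libraries, camera passed 0 lists, 3 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, passed 21. Splits of the 6 libraries that mixed the groups passed up to 12 lists. Each such split kept part of the difference between the groups, so these counts are no measure of chance. The 10 passing lists had the same counts of rising and falling members when adjusted over the list alone, except 15 rising YAP/TEAD targets and 20 falling oxidative phosphorylation genes. Among the other lists, adjusted over the list alone, 9 NF-kB genes rose and 9 fell, 13 MAPK output genes fell and 14 lysosome and autophagy genes rose. The median and the test differed in sign for NF-kB and cytokines (median 0.01, mean −0.01, test downward), ATF4 targets (median 0.01, mean −0.03, test downward) and other long noncoding RNAs (median −0.02, mean 0.07, test upward).

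No marker set of another cell type passed a test, and most sets had too few tested members. The neuron list, the only one with 5 tested members, did not pass (camera adjusted p = 0.391), and its most abundant marker TUBB3 stood at −0.08 ± 0.04 (SE; edgeR adjusted p = 0.119), or at −0.15 with library size alone, where it passed (adjusted p = 0.0067). Another neuron marker, SNAP25, fell by 0.57 ± 0.05 (adjusted p = 2.26e-09), and the other 3 tested did not pass. In TUBB3, 31.3% of 75-base stretches also occur in another gene. The most abundant marker of each other cell type was GJA1 for astrocytes (427 ± 2.55 against 205.5 ± 5.47 CPM; SD, n = 3), CD68 for microglia and leukocytes (332.5 ± 1.93 against 299 ± 13.1 CPM), CNP for oligodendrocytes (99.2 ± 2.79 against 67.6 ± 4.003 CPM), KDR for endothelium (5.35 ± 0.282 against 1.22 ± 0.122 CPM) and KRT8 for epithelium (3.88 ± 0.279 against 3.03 ± 0.534 CPM). All 5 were lower after knockdown (edgeR adjusted p between 2.03e-14 and 0.0166). Other markers went the other way in 3 of these sets. KRT7 of epithelium (0.94 ± 0.14, SE; edgeR adjusted p = 6.92e-06), VWF of endothelium (1.10 ± 0.27; adjusted p = 0.00123) and CD14 of microglia and leukocytes (1.71 ± 0.43; adjusted p = 0.00169) rose, the last at 2 to 19 counts in a library. The other markers that fell were SLC1A3 of astrocytes (−0.46 ± 0.06), CSF1R of microglia and leukocytes (−0.76 ± 0.06) and PECAM1 (−0.88 ± 0.17) and TEK (−0.82 ± 0.19) of endothelium. CD68 no longer passed with the correction for gene length (−0.07 against −0.15, adjusted p = 0.143). KRT8 no longer passed with DESeq2 (adjusted p = 0.0580), without siGL2 replicate A (adjusted p = 0.0520) or without siLINC00152 replicate C (adjusted p = 0.121), and 70.6% of the 75-base stretches of CD68 also occur in another annotated gene. AQP4, MOG, TYROBP and CD3E had 0 counts in all 6 libraries, which allows up to 0.0715 CPM in a library.

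Of 6 tested genes within 1 Mb of LINC00152, 4 rose, 1 fell and 1 did not pass. RMND5A, 676740 bases away on chromosome 2 (86720173 to 86778041, plus strand), rose from 16.2 ± 1.04 to 80.1 ± 2.04 CPM (SD, n = 3; edgeR adjusted p = 1.04e-17). EIF2AK3, a kinase sensor of unfolded proteins, rose by 0.82 ± 0.05 (SE), the histone demethylase gene KDM3A by 0.55 ± 0.04 and RNF103 by 0.21 ± 0.06. KRCC1 fell by 0.38 ± 0.06, and CHMP3, at 0.557 ± 0.146 against 0.620 ± 0.118 CPM, did not pass (edgeR adjusted p = 0.598). Genes of the opposite strand overlap 18.04% of exonic bases in RNF103 and 15.1% in EIF2AK3, and 10.8% of those of CHMP3 lie in another gene of the same strand.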

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

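Chosen after the results were seen were the list tests with an estimated correlation in fits that leave out a library or genes, the fits without genes whose 3′ UTR holds particular words and the list tests under library size alone or without the 20 most abundant genes. Genes named by the rule and cell type markers that passed were followed singly, and other genes named here were not. The direction of LINC00152, of each followed gene that passed and of the 10 lists was the same in every alternative in which it was tested. No gene called both in the main test and in an alternative changed sign. LINC00152 stayed between −2.64 and −2.45, and MIR4435-2HG, between −0.16 and −0.02, passed only with the correction for gene length (−0.158, adjusted p = 0.0084, and −0.158 with the block). DESeq2 called 4181 genes higher and 4115 lower, and gave 4277 genes no adjusted p. Leaving out a library gave 8294 to 9336 calls, 941 to 1037 of at least 2-fold, and 10 or 11 lists with the preset correlation. A test against a 1.5-fold change called 1506 genes, where 931 changed at least 2-fold in the main test. Without genes that hold any of the 4 words with the lowest z, 9292 genes were tested and 2828 were higher, 2831 lower and 549 changed at least 2-fold. Fewer genes were tested, and the calls dropped alike in both directions. Such genes made up 55.7% of the 2-fold falls and 47.4% of the 2-fold rises searched (37.9% and 47.2% expected from shuffles), against 39.1% of all genes searched. Camera with an estimated correlation passed 0 lists, with 3 at an unadjusted p under 0.05. It also passed 0 in each fit without a library or without carriers of the words (2 to 6 at an unadjusted p under 0.05). Fry passed 21, where the preset correlation passed 10, and the cause was not tested. The estimated correlations rested on few libraries and moved with them. Without siGL2 replicate A, that of the RNA interference list went from 0.37 to −0.03 and that of oxidative phosphorylation from 0.56 to 0.09. Among the 10 lists, those of G1/S, G2/M and hypoxia moved upward and the rest downward. Among the genes followed singly, the others that crossed the threshold were TUBB3 with library size alone (−0.15), KRT8 with DESeq2 (−0.36), without siGL2 replicate A (−0.30) and without siLINC00152 replicate C (−0.24), CD68 with the length correction (−0.07) and TCF4 without siLINC00152 replicate A (−0.11). Whether genes named outside the rule crossed it was not checked, apart from cell type markers that passed. The letters were not shown to pair the samples: deviations of same-letter libraries correlated at 0.157 (A), −0.096 (B) and 0.219 (C), and siLINC00152 replicate B correlated best with siGL2 replicate C (0.179). Replicates A and C of siLINC00152 did correlate best with the siGL2 replicate of their letter. On the second principal component (5.99% of variance) the A libraries stood at 12.9 (siGL2) and 10.8 (siLINC00152), and the rest between −9.21 and −2.90. Something shared by the A libraries therefore stays open. With the letter as a block, 4571 genes were higher, 4584 lower and 941 changed at least 2-fold, and 10 lists passed. The 6 libraries make 10 splits of 3 against 3, so no share under 0.05 can be reached. The real split called 4529 genes higher, 4529 lower and 931 of at least 2-fold, against at most 1 in any other split, each count reached by 1 split. It passed 10 lists, a count that 3 of the 10 splits reached, the highest other being 12, with siGL2 replicate A beside siLINC00152 replicates A and C. Every other split mixed the groups, which widened the spread within its sides and left part of the group difference in its contrast. The gene and list counts of those splits therefore do not show what a grouping without any difference would give. At this depth and spread, with 3 libraries in each group, simulated changes of the smallest size were recovered in 62% of genes, and what part of the loss depth accounts for was not tested. The simulation changed 50 genes at each of 4 fold sizes, far fewer than passed here, so this share need not hold for the real comparison.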

Other observations

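Genes of the RNA interference machinery were higher after knockdown. Of 13 tested members, 9 rose, 2 fell and 2 did not pass, with a median log2 fold change of 0.65 (camera adjusted p = 0.00127; adjusted p = 0.531 with an estimated correlation). Without genes that hold GTGTGTC, TGAAAGA, TGTGTCA or CTGAAAG in the 3′ UTR, a fit chosen after the results were seen, 5 members were left with a median of 0.09 and the list did not pass (camera adjusted p = 0.3497). Over all genes searched these words went with lower adjusted changes, so this fit does not tie the rise to them. Without genes that hold TGGTGCT, the word with the highest z, 7 members were left with a median of 0.71 (camera adjusted p = 0.626 with an estimated correlation). DICER1, which cuts microRNA precursors, rose by 1.38 ± 0.08 (SE), from 68.8 ± 9.84 to 179 ± 5.14 CPM (SD, n = 3). The silencing scaffold genes TNRC6A (0.98 ± 0.05) and TNRC6B (0.93 ± 0.05) and the Argonaute gene AGO4 (0.83 ± 0.06) rose, TARBP2 (−0.59 ± 0.05) and DGCR8 (−0.17 ± 0.05) fell, and PRKRA (0.09 ± 0.05) and DROSHA (−0.03 ± 0.05) did not pass.

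Other long noncoding RNAs went both ways, with 5 of 16 higher and 7 lower (camera adjusted p = 0.817). NEAT1, the scaffold of nuclear paraspeckles, rose 2.97-fold, from 558 ± 25.05 to 1654 ± 176 CPM (SD, n = 3; edgeR adjusted p = 6.21e-13). NORAD (0.70 ± 0.04, SE) and OIP5-AS1 (0.61 ± 0.05) also rose, and DANCR fell by 0.76 ± 0.05. In NORAD, 15.8% of 75-base stretches also occur in other genes. Of 25 lysosome and autophagy genes, 13 rose and 7 fell (camera adjusted p = 0.294). The autophagy kinase gene ULK1 (1.21 ± 0.06), GABARAPL1 (1.05 ± 0.06) and CTSA (0.63 ± 0.05) rose, and the cholesterol transporter gene NPC1 fell by 0.94 ± 0.05. Genes of the opposite strand overlap 28.5% of exonic bases in CTSA and 11.9% in DANCR.

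Tests chosen after the results were seen are those of both siRNA strands, of pairing between miR-29 and LINC00152, and of many microRNA families, the counts of genes that hold a word, and the fits without such genes. The tests on RMND5A were taken up because of its rise, so they were not chosen blind to the results either.

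After adjustment for 3′ UTR length and GC content, lower changes went with short words in the 3′ UTR: the lowest z among 16149 words was −8.56, for GTGTGTC (mean adjusted log2 change −0.11 over 1361 genes), followed by TGAAAGA (−8.48), TGTGTCA (−7.61) and CTGAAAG (−7.19), against −5.16 for the lowest in 100 shuffles, while the unadjusted medians of their carriers lay between −0.03 and 0.01. Of 300 genes that fell at least 2-fold, 167 held any of the 4 words, 53.4 more than the 113.6 expected from their mean share among genes of similar 3′ UTR length and GC content, where picking 4 words again in each of 100 shuffles gave an excess of 17.3 on average and of 30.3 at most, and 126 of 266 genes that rose at least 2-fold held one, with 125.65 expected from shuffles. This is what seed sites of the LINC00152 siRNAs in other transcripts would give, but the siRNA sequences are not in the labels, 56.2% of tested words occur in some LINC00152 transcript, and GTGTGTC occurs in 3 of 38. Joined, the 4 words make 2 words of 8 bases, and both stand in all 3 LINC00152 transcripts tied to RefSeq, CTGAAAGA as such and GTGTGTCA as its reverse complement TGACACAC, where 2.93% of words of that length stand on either strand, so off-target pairing by a guide and by the opposite strand of an siRNA may be a candidate explanation for part of the falls. Other explanations stay open, since 4 of the 12 largest falls (HAS1, IL1B, PHGDH and RFX8) hold none of the 4 words. Without the genes that do, 2831 of 9292 tested genes were still lower and the falling G1/S and G2/M lists still passed with the preset correlation (camera adjusted p = 0.142 and 0.244 with an estimated one). Genes without the words could also fall indirectly, through genes that hold them. These counts therefore cannot tell off-target pairing from a loss of LINC00152 itself, which stays open as the design's explanation.

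Genes that rose were marked by TGGTGCT, the site of miR-29, with the highest z of all words (8.79, against 4.67 for the highest in shuffles) and a mean adjusted log2 change of 0.10 over 1740 genes. It was held by 84 of 266 genes that rose at least 2-fold, among them COL5A1, which is 32.2 more than expected, where picking a word again in each of 100 shuffles gave an excess of 22.7 at most. The seed site of the siGL2 guide gave no sign of relief from that guide (z of −0.0363 over 150 genes, with the guide sequence taken from general knowledge and not the labels). No word held by so few genes was planted in the test of the search, so a small effect could be missed. The seed site of the opposite siGL2 strand stood in 26 genes, under the 50 needed, and was not tested. The sites of 19 other widely expressed microRNA families had a median z of 2.07, above 100% of 100000 random sets of words, and 18 of 19 lay above 0. Some of these sites overlap, such as TTTGCAC, TTGCACT and TGCACTG, or TGCTGCT and ATGCTGC, so they are not independent. Each was held by 1007 to 2651 genes, where a tested word needed only 50. The random sets allowed for neither point, so shares of random sets and the 18 of 19 may overstate the evidence. A weaker effect of many microRNAs, as transfected siRNAs could give by competing for Argonaute proteins, may contribute. Both groups received siRNA, the amounts are not in the labels, microRNAs were not measured, and 6 families of other tissues had a median z of 0.737 (above 94.8% of random sets), so a biological change in miR-29 stays open, as does its direct pairing with LINC00152, since the site stands in 0 of 3 RefSeq-tied but in 1 of 38 annotated transcripts and the counts do not tell transcripts apart.

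RMND5A, near LINC00152, rose 4.95-fold. Shared reads are argued against, since 0 of its 6728 stretches of 75 bases occur in LINC00152 or MIR4435-2HG. The other 5 tested genes within 1 Mb had a median log2 fold change of 0.21. EIF2AK3 (0.82), KDM3A (0.55) and RNF103 (0.21) rose, KRCC1 fell (−0.38) and CHMP3 did not pass. These values argue against a rise of the whole neighbourhood as large as that of RMND5A (2.31). So few genes, with CHMP3 at low counts, cannot tell whether there was a smaller regional rise. The 3′ UTR of RMND5A, of 4633 bases, holds TGGTGCT, the sites of 10 of 20 microRNA families and also 1 of the words with the lowest z. How many such sites a 3′ UTR of that length would hold by chance was not computed. An effect of these sites or of LINC00152 on its neighbour was not tested.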
